A study of Mus musculus with 12 samples.

How the data were processed

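Messenger RNA was measured in 12 libraries of im-TEC, a mouse line of conditionally immortalized kidney tubular epithelial cells, in 4 groups of 3: control, TGFβ, the NNMT inhibitor 5-amino-1-methylquinolinium, and both. Total RNA from cells in 6-well plates (100 ng) was made into QuantSeq 3′ FWD libraries, which read the end of each transcript, so that counts do not scale with gene length. Per the labels, the authors aligned the reads with STAR and counted them per gene with HTSeq, and the deposited values are whole-number counts. Versions are not stated. The build named is GRCh38, a human build, although the genes carry mouse identifiers, so no positions are given here. The strand used for counting is not stated, so reads of overlapping genes may be assigned to either. Of 59 named genes checked, 21 overlap another annotated gene, 6 of them on the same strand (*Ankrd39*, *Ccbe1*, *Cdkl1*, *Col4a1*, *Kif26b* and *Sned1*). Nothing says that the replicates came from separate cultures, so p-values measure only the spread between these samples.

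The table held 55487 genes, of which 23630 had a count, and 55141 identifiers were matched to a symbol. The identifiers of the genes followed throughout are *Nnmt* ENSMUSG00000032271, *Ccn2* ENSMUSG00000019997, *Fn1* ENSMUSG00000026193, *Col1a1* ENSMUSG00000001506, *Col4a1* ENSMUSG00000031502, *Acta2* ENSMUSG00000035783, *Tagln* ENSMUSG00000032085, *Cdkn1a* ENSMUSG00000023067, *Cdkn2a* ENSMUSG00000044303, *Cdkn2b* ENSMUSG00000073802, *Havcr1* ENSMUSG00000040405, *Mki67* ENSMUSG00000031004, *Lmnb1* ENSMUSG00000024590, *Tgfb1* ENSMUSG00000002603, and among the others *Postn* ENSMUSG00000027750, *Ly6a* ENSMUSG00000075602, *Aqp1* ENSMUSG00000004655, *Ankrd1* ENSMUSG00000024803, *Sox9* ENSMUSG00000000567. Totals per library ranged from 2584117 to 11866903 counts in genes, and 3 counts in a library corresponded to 0.253 to 1.16 CPM. Floors for genes at 0 were set at 3 counts over the 3 libraries of a group, so leaving out 1 library raises them. Values at a floor are not confidence bounds, and exact 95% counting intervals reach nearer to no change. Both cover counting error only. No pair of replicates was a duplicate, since their counts differed by a chi-square per degree of freedom of 3.3 to 44.4.

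Genes were filtered with filterByExpr, which left 13581, scaled by TMM and tested in edgeR 4.0.16 (R 4.3.3, limma 3.58.1) by quasi-likelihood F-tests with robust dispersion in 1 model of 4 group means. Genes were called at a Benjamini-Hochberg adjusted p below 0.05. The comparisons were TGFβ with control, inhibitor with control, the combined group with TGFβ, the combined group with inhibitor, and the interaction, the difference between the inhibitor effects with and without TGFβ. CPM used TMM-scaled library sizes, and log2 CPM a prior count of 3. Genes were named from a fixed panel, from the 6 largest rises and falls of each comparison at 10 CPM or more whose replicates did not overlap, which chance gives in 10% of genes for 3 against 3 (0.1), from called members of each list, and from the smallest adjusted p of the interaction.

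Of 31 gene lists, 30 had at least 5 tested members and were run in camera with a preset correlation of 0.01. They cover SMAD targets, matrix, basement membrane, contractile, epithelial, proximal tubule, loop and distal, fibroblast, immune, podocyte, injury, senescence arrest and secretion, mitosis, DNA replication, NAD and methionine metabolism, oxidative phosphorylation, mitochondrial transcripts, fatty acid oxidation, glycolysis, cholesterol, NRF2, stress response, interferon, NF-kB, aryl hydrocarbon receptor, lysosome, histone methylation and ribosomal genes. The endothelial list had 3 tested genes and was not run, and 1 list gene had no match. Counts of list members refer to tested genes, which are a small part of some lists. Tested were 12 of 42 proximal tubule, 5 of 29 loop and distal, 7 of 20 fibroblast and 5 of 22 immune genes. Results of some genes are not reported here. The comparisons, tests, gene panel, lists and most alternatives were chosen before the data were examined. Camera for the combined group with inhibitor and for the interaction, quality weights, thinning, leaving out TGFβ replicates 2 and 3, and most tests of explanations in the closing part, which names them, were added later.

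The procedure was tested on simulated data. Known changes of 1.5, 2 and 4-fold were recovered in 31.3, 74.6 and 92.4% of genes for TGFβ with control, and in 8.96, 32.8 and 83.3% for the interaction. A list shifted by 0.3 on the log2 scale had a camera adjusted p of 2.15e-14, and 0 of 29 other lists were called. Among the called genes, 7 of 139 were false for TGFβ with control and 5 of 88 for the interaction. Genes were simulated independently, so the simulation does not test false list calls where the genes of a list move together. Each gene had the same spread in all groups, so it also does not test unequal spread between groups. Alternatives were DESeq2 1.42.0, limma-voom with and without quality weights, other scalings and filters, a fold threshold, only the 2 groups compared, a replicate block, leaving out each library, and for lists an estimated correlation and fry. No scaling moved the median of all genes by over 0.1 on the log2 scale, and the largest median was -0.0719 with library sizes alone.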

Results

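Gene expression was measured by 3′ RNA sequencing in im-TEC, mouse conditionally immortalized tubular epithelial cells kept at 33 °C with interferon-gamma. Before seeding, they spent 7 days at 37 °C without it, which lowers the activity of their SV40 large T antigen. They were then treated for 48 h in 4 groups of 3 libraries: untreated control, TGFβ at 10 ng/mL, the NNMT inhibitor 5-amino-1-methylquinolinium at 50 µM, and TGFβ with the inhibitor (the combined group). Counts assigned to genes were 8543476, 7936902 and 9458864 per library in the controls and 9059721, 8412804 and 9289150 with the inhibitor. They were 9300982, 11866903 and 2584117 with TGFβ and 8901080, 9257735 and 7838352 in the combined group. Levels are CPM, counts scaled to a common library size, as mean ± SD of 3 libraries, and changes are log2 fold changes ± SE from edgeR with its adjusted p.

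The 4 groups separated on the first 2 principal components, which held 56.5% and 13.5% of the variance. Replicates differed most in the TGFβ group, whose biological coefficient of variation was 0.228 against 0.0657 in the controls, 0.0885 with the inhibitor and 0.112 in the combined group. Over 8775 protein-coding genes the median absolute log2 difference from TGFβ replicate 1 was 0.27 for replicate 2 and 0.191 for replicate 3, and 0.341 between replicates 2 and 3, against at most 0.116 between controls. TGFβ replicate 3 was also the shallowest library. Reads outside annotated genes made up 21.8 ± 0.907% of the counts with TGFβ and 22.1 ± 0.929% in the combined group, against 25.8 ± 0.252% in the controls and 25.7 ± 1.44% with the inhibitor.

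**Figure D1:**
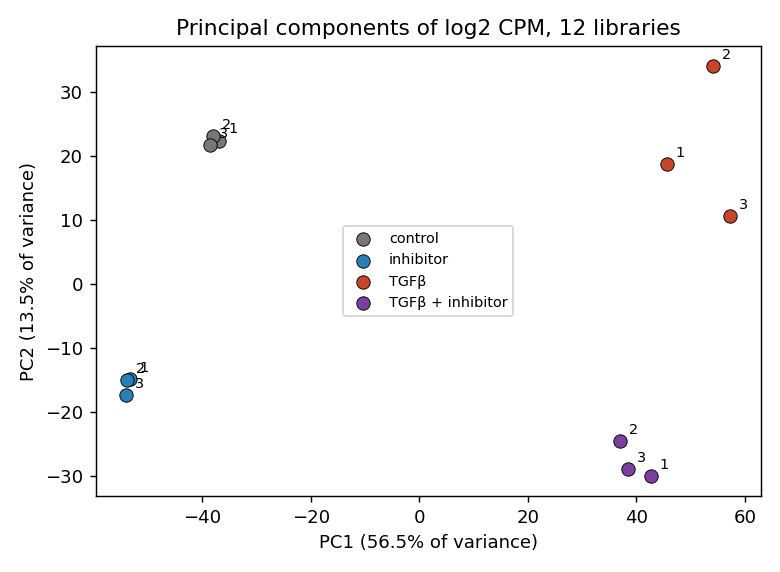
First and second principal components of log2 CPM over the tested genes, 1 point per library, numbered by replicate and coloured by group. The TGFβ-treated libraries lie on the right, and TGFβ replicate 2 lies away from the other TGFβ libraries on the second component.

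The effect of TGFβ alone was read from TGFβ against control. Most matrix and contractile genes fixed in advance rose, while the basement membrane collagen *Col4a1*, given below, fell. *Col1a1*, a chain of fibrillar collagen I, rose 36.4-fold from 4.54 ± 1.62 to 165 ± 19.3 CPM (5.18 ± 0.24, adjusted p 1.6e-10), and *Acta2*, the smooth muscle actin of myofibroblasts, rose 20.0-fold from 43.6 ± 1.00 to 873 ± 129 CPM (4.32 ± 0.14, adjusted p 4.04e-13). The actin-binding *Tagln* rose 9.32-fold, the matricellular *Ccn2* 6.77-fold, *Postn* (periostin) 6.74-fold and *Fn1* (fibronectin) 3.09-fold, with adjusted p of 1.61e-05, 0.00384, 1.6e-10 and 1.97e-09. *Pmepa1*, a feedback inhibitor of TGFβ signalling, rose 10.5-fold (adjusted p 7.17e-12), while *Id2* and *Id1*, antagonists of helix-loop-helix factors, fell 8.66-fold and 2.78-fold (adjusted p 1.69e-12 and 1.7e-09). *Havcr1* (KIM-1), a marker of injured proximal tubule, rose 3.51-fold from 6.68 ± 0.621 CPM (adjusted p 0.000148).

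Of the 13581 genes tested, 4961 were called with TGFβ, 2636 up and 2325 down, of which 818 and 931 changed at least 2-fold. Scaling by library size alone gave 2144 up and 2811 down, and thinning every library to the shallowest 1880 up and 2005 down, so which direction led depended on the processing. Among the largest rises, *Lrrc32*, which anchors latent TGFβ at the cell surface, had 0 counts in the controls and 459 with TGFβ. It was 179-fold higher at the floor, with a counting interval from 145. *Fbxo40*, a muscle ubiquitin-ligase subunit, had 2 counts in the controls and 240 with TGFβ, a ratio of 140 with a counting interval of 38.5 to 1170. The sialic acid hydroxylase *Cmah* rose 87.7-fold, the protease *Ctsw* 83.4-fold, the acyl-CoA synthetase *Acsbg1* 64.6-fold and the skeletal actin *Acta1* 52.4-fold. Among the largest falls, *Inmt*, a methyltransferase of the same family as *Nnmt*, went from 1450 counts to 0. It was 413-fold lower at the floor, with a counting interval of the ratio up to 0.00298. The water channel *Aqp1* of the proximal tubule fell 39.4-fold from 1013 ± 46.9 to 25.2 ± 8.55 CPM (adjusted p 2.72e-09), the chemokine receptor *Ackr3* 48.5-fold and angiotensinogen (*Agt*) 36.0-fold. The calcification inhibitor *Mgp* fell 78.9-fold, or 184-fold without TGFβ replicate 2. The kinase *Cdkl1* fell 42.8-fold, or 26.2-fold and 154-fold without TGFβ replicate 1 or 2. The basement membrane collagen *Col4a1* fell 2.73-fold (adjusted p 0.000463).

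Genes of cell cycle arrest went both ways with TGFβ, and a division marker rose. The inhibitors of cyclin-dependent kinases *Cdkn2b* and *Cdkn2a* rose 1.74-fold and 1.54-fold (adjusted p 2.88e-06 and 0.00135), while the related *Cdkn2c* fell 2.12-fold (adjusted p 1.86e-06) and the proliferation marker *Mki67* rose 1.68-fold (adjusted p 0.00266). *Cdkn1a* rose 1.24-fold (adjusted p 0.0189), and its call ended without control replicate 1 (0.0971) or TGFβ replicate 1 (0.0809). *Lmnb1*, a lamin that falls in senescent cells, was not called (0.40 ± 0.17, adjusted p 0.0731), but was without TGFβ replicate 3 (0.000991). *Tgfb1* was not called (adjusted p 0.274), but was without TGFβ replicate 3 (0.0373). *Nnmt*, which encodes the methyltransferase that the inhibitor blocks, stood at 26.2 ± 3.01 CPM in the controls and 29.0 ± 4.29 with TGFβ, and was not called (adjusted p 0.609). With the inhibitor alone it stood at 19.1 ± 3.51 CPM, lower in 3 of 3 libraries than in any control, and was not called (adjusted p 0.0907), though it was when only these 2 groups were fitted. *Cdh1*, the epithelial cadherin, had too few counts to be tested, 1 in the controls, 4 with TGFβ, 3 with the inhibitor and 1 in the combined group.

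**Figure D2:**
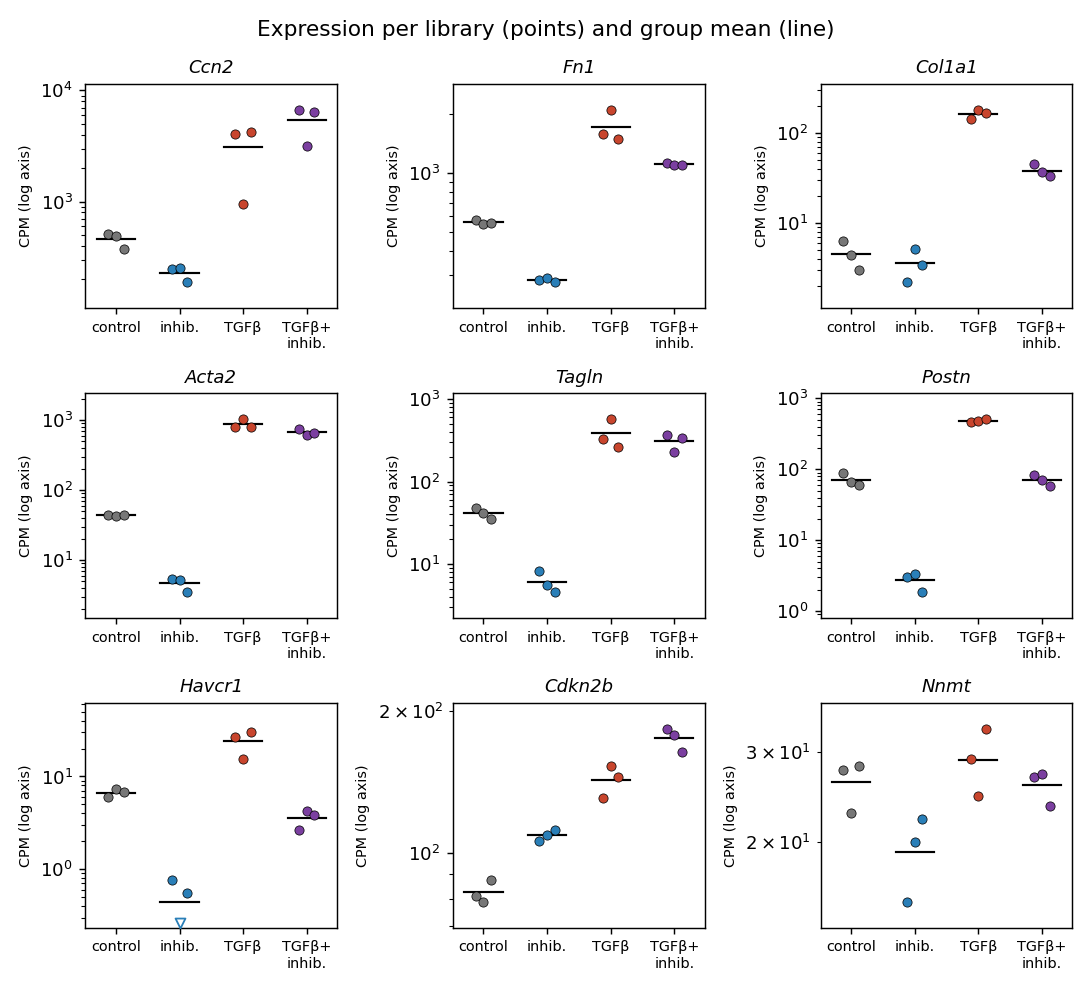
CPM on a log axis for 9 genes in the 4 groups, with 1 point per library and a line at the group mean. An open triangle at the foot of the axis marks a library with 0 counts, and *Postn*, *Fn1* and *Havcr1* lie lower in the combined group than with TGFβ alone.

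In 30 gene lists written beforehand, camera called 16 with TGFβ, 9 up and 7 down, of which 13 held with an estimated correlation between genes. Interferon-stimulated genes rose most, 41 up and 0 down of 49, and 42 and 0 adjusted over the list alone (median 1.76, adjusted p 6e-45), as in *Ifit1* (7.50-fold), *Irf7* (8.05-fold), *Gbp3* (7.28-fold) and *Cxcl10* (6.43-fold). Fibrillar collagen and matrix genes rose, 26 up and 4 down of 37, and 28 and 4 adjusted over the list alone (median 1.22, adjusted p 7.3e-16), including *Timp1* (5.20-fold) and *Col5a1* (4.33-fold). Mesenchymal and contractile genes such as *Tpm1* (3.23-fold) and *Actn1* (3.01-fold) rose, 18 up and 3 down of 27, and 19 and 3 adjusted over the list alone (adjusted p 1.7e-09). Genes of DNA replication rose, 42 up and 1 down of 45, and 43 and 1 adjusted over the list alone (adjusted p 9.3e-17), for example *Mcm3* (2.28-fold) and *Rrm1* (1.84-fold), as did mitotic genes, 35 up and 0 down of 37, and 35 and 0 adjusted over the list alone (adjusted p 4.2e-10). Cholesterol synthesis genes rose, 24 up and 1 down of 33, and 26 and 1 adjusted over the list alone (adjusted p 7.3e-09), for example *Cyp51* (2.63-fold). Secreted factors of senescent cells rose, 15 up and 8 down of 33, and 15 and 8 adjusted over the list alone (adjusted p 9e-04), among them *Inhba* (5.79-fold) and *Mmp9* (8.36-fold). Fibroblast markers rose, 3 up and 1 down of 7, and 3 and 1 adjusted over the list alone (adjusted p 0.01), *Nt5e* by 4.17-fold, though *Islr* fell 20.7-fold. Ribosomal protein genes rose, 16 up and 1 down of 48, and 16 and 1 adjusted over the list alone (adjusted p 0.022).

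Genes of tubule function and energy metabolism fell with TGFβ. Glycolysis and hypoxia genes fell, 1 up and 23 down of 32, and 1 and 23 adjusted over the list alone (median -0.90, adjusted p 1.3e-10), *Aldoa* by 3.14-fold and *Pdk1* by 4.43-fold. Targets of the antioxidant regulator NRF2 fell, 3 up and 19 down of 32, and 4 and 19 adjusted over the list alone (adjusted p 4e-07), the glutathione transferase *Gstm1* by 24.9-fold and *Nfe2l2*, which encodes NRF2, by 2.50-fold. Proximal tubule genes fell, 2 up and 6 down of 12, and 2 and 6 adjusted over the list alone (adjusted p 0.00037), the membrane peptidase *Mme* by 3.40-fold. Nuclear genes of oxidative phosphorylation fell, 0 up and 35 down of 75, and 0 and 36 adjusted over the list alone (adjusted p 9.7e-06), *Ndufb8* by 2.25-fold, but not with the estimated correlation (adjusted p 0.18). Fatty acid oxidation genes fell, 2 up and 13 down of 32, and 2 and 14 adjusted over the list alone (adjusted p 0.00094, 0.0499 with the estimated correlation), and the mitochondrial coactivator *Ppargc1a* fell 21.3-fold from 256 ± 12.3 to 12.1 ± 3.23 CPM. Tubular injury genes fell on balance, 7 up and 11 down of 23, and 9 and 11 adjusted over the list alone (adjusted p 0.027, 0.057 with the estimated correlation), with *C3* down 8.96-fold and *Cd44* up 3.28-fold. That call ended without control replicate 1 (0.0525), control replicate 2 (0.0525) or TGFβ replicate 2 (0.112). Only 5 of 29 loop of Henle and distal tubule markers were tested. As a list they fell, 1 up and 2 down, and 1 and 2 adjusted over the list alone (adjusted p 0.027, 0.1 with the estimated correlation). Their call ended without control replicate 1 (0.103), control replicate 2 (0.0713), control replicate 3 (0.122) or TGFβ replicate 3 (0.184). This call and that of injury genes also ended without TGFβ replicates 2 and 3 together.

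The other 14 lists were not called with TGFβ (adjusted p 0.075 to 0.92), with the counts adjusted over the list alone given after those over all genes. SMAD targets had 12 up and 6 down (12 and 7), and were called without TGFβ replicate 2 (0.0377) and without TGFβ replicates 2 and 3 together. Basement membrane genes had 4 up and 6 down (4 and 6), epithelial junction genes 5 and 7 (5 and 7), podocyte markers 2 and 5 (2 and 5) and immune cell markers 1 and 3 (1 and 3). Senescence arrest and p53 targets had 9 up and 8 down (10 and 8), with *Gadd45g* 4.79-fold up and *Bbc3* 2.25-fold down. NAD metabolism genes had 3 up and 6 down (3 and 6), among them *Nampt*, the enzyme of the salvage pathway, 2.54-fold down, and methionine and polyamine genes 10 and 3 (9 and 3). Stress response genes had 11 up and 8 down (12 and 8), aryl hydrocarbon receptor targets 2 and 1 (2 and 1), NF-kB targets 4 and 5 (5 and 5) and histone methylation genes 7 and 9 (8 and 9), 4 lists in which the median or mean had the opposite sign to the test. Lysosomal genes had 4 up and 12 down (4 and 13), a list called without TGFβ replicate 2 (0.0227), and without TGFβ replicates 2 and 3 together, and mitochondrially encoded transcripts 0 and 1 (0 and 1). Fry, which sets no list against the other genes, called 8 of these 14. The endothelial list had 3 of its 18 genes tested and was not run.

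The effect of the inhibitor alone was read from inhibitor against control. Contractile and matrix genes fell below their control levels: *Acta2* fell 9.29-fold to 4.70 ± 1.05 CPM (-3.21 ± 0.16, adjusted p 3.23e-10) and *Postn* 26.1-fold to 2.75 ± 0.783 CPM (-4.70 ± 0.20, adjusted p 1.02e-10). The actin-binding *Cnn1* and *Tagln* fell 14.5-fold and 6.82-fold (adjusted p 2.96e-07 and 0.000975), and *Fn1* 1.97-fold (adjusted p 1.46e-05). The injury marker *Havcr1* fell 14.4-fold, or 22.6-fold without inhibitor replicate 1 (adjusted p 3.46e-05). The surface protein *Ly6a* (Sca-1) fell 8.78-fold from 171 ± 9.89 to 19.4 ± 2.84 CPM (adjusted p 1.02e-10) and the uroplakin *Upk3b* 8.33-fold. The amino acid transporter *Slc6a18* fell 29.9-fold, or 52.7-fold without inhibitor replicate 2. Rises were smaller, with the pro-apoptotic *Bmf* up 4.56-fold (adjusted p 0.000193), the kinesin *Kifc2* 2.96-fold, the desmosomal *Ppl* 2.79-fold, the matrix protein *Sned1* 2.74-fold and the zinc exporter *Slc30a1* 2.25-fold.

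Several weaker calls with the inhibitor ended when 1 library was left out. *Cdkn2b* rose 1.32-fold (adjusted p 0.0124), a call that ended without control replicate 1 (0.0644), control replicate 2 (0.0796), inhibitor replicate 2 (0.0523) or inhibitor replicate 3 (0.0624). *Lmnb1* fell 1.59-fold (adjusted p 0.0225), a call that ended without control replicate 1 (0.101), control replicate 2 (0.083), inhibitor replicate 1 (0.0583) or inhibitor replicate 3 (0.0809). The small GTPase *Rasl11b* rose 2.21-fold (adjusted p 0.0482), not called without control replicate 1 (0.153), control replicate 2 (0.147), control replicate 3 (0.102), inhibitor replicate 1 (0.115), inhibitor replicate 2 (0.119) or inhibitor replicate 3 (0.175). *Col1a1* (adjusted p 0.586), *Ccn2* (0.321), *Col4a1* (0.0983), *Cdkn1a* (0.36), *Cdkn2a* (0.875), *Mki67* (0.165) and *Tgfb1* (0.566) were not called.

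In all, 1123 genes were called with the inhibitor, 335 up and 788 down, of which 47 and 318 changed at least 2-fold. Scaling by library size alone gave 204 up and 1036 down, and fitting only these 2 groups 1287 up and 1644 down. The model of all 12 libraries shares its spread between groups. Its biological coefficient of variation of 0.137 exceeds those of the controls (0.0657) and the inhibitor libraries (0.0885), so its p-values here may be too large. Without control replicate 1, 2 or 3, the count was 594, 591 or 642, and without inhibitor replicate 1, 2 or 3 it was 684, 624 or 624. Mitochondrially encoded transcripts made up 11.8 ± 0.557% of the counts with the inhibitor against 7.61 ± 0.52% in the controls, a ratio of 1.55, and the nuclear *Malat1* 3.43% against 2.07%, a ratio of 1.66. Each had an exact two-sided permutation p of 0.1, the smallest that 3 libraries against 3 allow.

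Camera called 14 lists with the inhibitor, 2 up and 12 down, of which 13 held with an estimated correlation. Mesenchymal and contractile genes fell, 0 up and 15 down of 27, and 0 and 19 adjusted over the list alone (median -0.66, adjusted p 1.3e-26), among them *S100a4* (4.90-fold) and *Actn1* (1.72-fold). Cholesterol synthesis and sterol genes fell, 0 up and 18 down of 33, and 0 and 21 adjusted over the list alone (adjusted p 4.4e-15), the sterol oxidase *Msmo1* by 1.57-fold. Secreted factors of senescent cells fell, 1 up and 15 down of 33, and 1 and 19 adjusted over the list alone (median -0.70, adjusted p 3.8e-12), including *Inhba* (3.05-fold) and *Igfbp2* (3.16-fold). Matrix genes fell, 2 up and 11 down of 37, and 2 and 14 adjusted over the list alone (adjusted p 2.2e-10), *Mmp2* by 1.99-fold and *Loxl1* by 1.97-fold. Tubular injury genes fell, 1 up and 12 down of 23, and 2 and 14 adjusted over the list alone (adjusted p 1.5e-10), *Vcam1* by 3.21-fold, *Cd44* by 2.12-fold and *Spp1* by 1.82-fold. Interferon-stimulated genes fell, 0 up and 18 down of 49, and 1 and 23 adjusted over the list alone (adjusted p 3.6e-09, 0.063 with the estimated correlation, which ended the call), *Ifitm3* by 2.04-fold and *Isg15* by 2.02-fold. NF-kB targets fell, 0 up and 7 down of 21, and 0 and 10 adjusted over the list alone (adjusted p 4.3e-07), as did mitotic genes, 0 up and 6 down of 37, and 0 and 8 adjusted over the list alone (adjusted p 4.2e-06), and DNA replication genes, 0 up and 7 down of 45, and 0 and 11 adjusted over the list alone (adjusted p 0.00046), *Tk1* by 1.81-fold.

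Smaller lists also fell with the inhibitor: proximal tubule genes, 0 up and 3 down of 12, and 0 and 5 adjusted over the list alone (adjusted p 0.0012), with the endocytic adaptor *Dab2* down 1.64-fold, podocyte markers, 0 up and 2 down of 9, and 0 and 3 adjusted over the list alone (0.0045), and fibroblast markers, 0 up and 2 down of 7, and 0 and 2 adjusted over the list alone (0.0096). Mitochondrially encoded transcripts rose, 5 up and 0 down of 9, and 7 and 0 adjusted over the list alone (median 0.65, adjusted p 2e-08), *mt-Co1* by 1.80-fold, while nuclear genes of oxidative phosphorylation were not called as a list (adjusted p 0.93). Glycolysis and hypoxia genes rose, 6 up and 1 down of 32, and 8 and 1 adjusted over the list alone (adjusted p 0.0096), *Bnip3* by 1.68-fold, and *Pdk1* by 1.66-fold. With every library thinned to the shallowest, the podocyte (0.223) and glycolysis calls (0.0742) ended. The other 15 lists were not called (adjusted p 0.08 to 0.93): ribosomal, loop and distal, fatty acid oxidation, NRF2, SMAD, basement membrane, epithelial junction, immune, methionine and polyamine, stress response, aryl hydrocarbon receptor, lysosomal and histone methylation genes, NAD metabolism (1 up, 1 down) and senescence arrest (3 up, 5 down). Methionine and polyamine genes (adjusted p 0.08) were called without control replicate 2 (0.0445). Fry called 6 of the 16 lists that camera did not. For SMAD targets, senescence arrest and histone methylation genes, the median or mean had the opposite sign to the test.

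**Figure D3:**
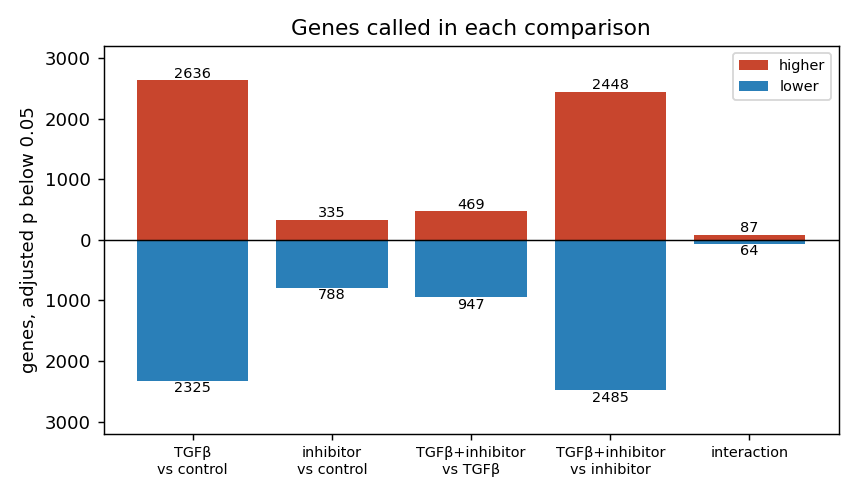
Number of genes called higher (red, above 0) and lower (blue, below 0) at an edgeR adjusted p below 0.05 in each comparison. TGFβ changed 4961 genes alone and 4933 in the presence of the inhibitor, and the interaction held 151.

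Whether the inhibitor moved transcripts in TGFβ-treated cells was read from the combined group against TGFβ. Some matrix genes that TGFβ had raised were lower, as was the injury marker *Havcr1*. *Col1a1* fell 4.28-fold to 38.4 ± 6.13 CPM (-2.10 ± 0.20, adjusted p 6.52e-06), *Postn* 6.84-fold to 70.6 ± 12.2 CPM (-2.77 ± 0.15, adjusted p 5.11e-09) and *Havcr1* 6.52-fold to 3.59 ± 0.831 CPM (-2.71 ± 0.33, adjusted p 4.33e-05). *Fn1* fell 1.56-fold (adjusted p 9e-04). In contrast, *Ccn2* (0.81 ± 0.51, adjusted p 0.377) and *Tagln* (-0.31 ± 0.28, 0.549) were not called. *Acta2* missed the threshold (-0.37 ± 0.12, adjusted p 0.052), passed it in 9 of 18 alternatives, and was called lower without TGFβ replicate 1 (0.0384) or TGFβ replicate 3 (0.0245).

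Among genes at 10 CPM or more in the higher group and with replicates that did not overlap, the largest falls with the inhibitor on top of TGFβ were in *Ly6a*, 19.3-fold from 126 ± 15.5 to 6.52 ± 1.40 CPM (adjusted p 7.62e-12), the potassium channel *Kcnj15* (15.7-fold), the short-chain collagen *Col8a1* (15.7-fold), the interleukin-33 receptor *Il1rl1* (10.5-fold), *Lrrc32* (7.26-fold) and the interferon-inducible *Slfn2* (7.14-fold). The largest rises among such genes were in the secreted *C1qtnf3* (3.64-fold, adjusted p 0.000262), the myofibroblast-associated *Nrep* (2.79-fold), the stress-induced *Gadd45a* (2.57-fold), *Igfbp5* (2.40-fold), *Ankrd39* (2.28-fold) and *Sned1* (2.26-fold). *Cdkn2b* was not called (0.29 ± 0.09, adjusted p 0.0566) but was without TGFβ replicate 2 (0.0106). *Mki67* was not called (-0.54 ± 0.17, adjusted p 0.0555) but was without TGFβ replicate 1 (0.0264), TGFβ replicate 3 (0.0236) or combined replicate 2 (0.0296). *Lmnb1* was not called (adjusted p 0.27) but was without TGFβ replicate 3 (0.0136). *Nnmt* (0.643), *Cdkn1a* (0.699), *Cdkn2a* (0.944), *Col4a1* (0.793) and *Tgfb1* (0.472) were not called. In all, 1416 genes were called, 469 up and 947 down, of which 47 and 402 changed at least 2-fold. Fitting only these 2 groups gave 408 genes, 76 up and 332 down. The biological coefficient of variation in the model of all 12 libraries, 0.137, is below the 0.228 of the TGFβ libraries. Its p-values here may therefore be too small. The count was 856 without combined replicate 1 and 762 without combined replicate 3. *Malat1* made up 2.44% of the counts against 1.35% with TGFβ, a ratio of 1.8 (exact two-sided permutation p 0.1), and mitochondrially encoded transcripts 8.13 ± 0.763% against 6.83 ± 1.33% (ratio 1.19, exact p 0.3).

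Camera called 20 lists in the combined group against TGFβ, 4 up and 16 down, of which 13 held with an estimated correlation. Interferon-stimulated genes fell, 0 up and 35 down of 49, and 0 and 39 adjusted over the list alone (median -0.70, adjusted p 6.2e-34), *Ifitm3* by 2.48-fold and *Ifit3* by 2.41-fold. DNA replication genes fell, 0 up and 25 down of 45, and 0 and 34 adjusted over the list alone (median -0.52, adjusted p 1.8e-14), *E2f8* by 2.48-fold and *Tk1* by 2.01-fold, and mitotic genes fell, 0 up and 13 down of 37, and 0 and 19 adjusted over the list alone (adjusted p 1.2e-08), *Foxm1* by 1.52-fold. Cholesterol synthesis genes fell, 1 up and 15 down of 33, and 1 and 21 adjusted over the list alone (adjusted p 2e-08), the desaturase *Scd1* by 2.54-fold. Matrix genes fell, 3 up and 15 down of 37, and 4 and 18 adjusted over the list alone (adjusted p 5.7e-07), *Adamts1* by 2.33-fold. Tubular injury genes fell, 0 up and 10 down of 23, and 3 and 11 adjusted over the list alone (adjusted p 1.4e-06), *Spp1* by 2.56-fold, and secreted factors of senescent cells fell, 2 up and 10 down of 33, and 4 and 16 adjusted over the list alone (adjusted p 2.4e-05), *Cxcl16* by 2.10-fold and *Inhba* by 1.78-fold. Proximal tubule genes fell on balance, 1 up and 4 down of 12, and 1 and 5 adjusted over the list alone (adjusted p 0.00041). Of these, *Slc6a18* had 94 counts with TGFβ and 0 in the combined group, 33.9-fold lower at the floor, while the endocytic receptor *Lrp2* rose (0.58 ± 0.09). Epithelial junction genes fell, 1 up and 5 down of 22, and 1 and 8 adjusted over the list alone (adjusted p 0.0064), *Krt7* by 4.13-fold.

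Markers of other cell types fell in the same comparison: fibroblast markers, 0 up and 2 down of 7, and 0 and 5 adjusted over the list alone (adjusted p 0.00014), immune markers, 0 up and 2 down of 5, and 0 and 3 adjusted over the list alone (0.0068), *Csf1r* by 1.91-fold, and podocyte markers, 1 up and 2 down of 9, and 1 and 5 adjusted over the list alone (0.0087). Loop and distal markers fell, 0 up and 3 down of 5, and 0 and 5 adjusted over the list alone (0.00049, 0.058 with the estimated correlation). Calls that the estimated correlation also ended were mesenchymal genes, 1 up and 5 down of 27, and 1 and 7 adjusted over the list alone (0.034 against 0.25), NRF2 targets, 0 up and 5 down of 32, and 0 and 6 adjusted over the list alone (0.047 against 0.28), and NF-kB targets, 1 up and 8 down of 21, and 2 and 10 adjusted over the list alone (0.0094 against 0.21), all down. The glutathione synthesis gene *Gclc* fell 2.31-fold. The mesenchymal call ended without TGFβ replicate 2 (0.28) or combined replicate 3 (0.0554). The NRF2 call ended without TGFβ replicate 1 (0.195), TGFβ replicate 2 (0.0515) or combined replicate 1 (0.144), and the NF-kB call without TGFβ replicate 1 (0.103). The podocyte call ended with every library thinned to the shallowest (0.07), as did the NRF2 call. Of the lists that rose, mitochondrially encoded transcripts, 4 up and 0 down of 9, and 4 and 0 adjusted over the list alone (adjusted p 0.00034), *mt-Nd5* by 1.56-fold, held with the estimated correlation.

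Calls of 3 rising lists ended with it: SMAD targets, 6 up and 1 down of 28, and 8 and 3 adjusted over the list alone (0.0094 against 0.1), with *Id1* up 1.45-fold, oxidative phosphorylation genes, 1 up and 0 down of 75, and 0 and 0 adjusted over the list alone (0.036 against 0.5), and stress response genes, 4 up and 2 down of 43, and 4 and 2 adjusted over the list alone (0.047 against 0.067), with the amino acid transporter *Slc38a2* up 1.41-fold. The call of oxidative phosphorylation genes ended without TGFβ replicate 1 (0.229) or combined replicate 2 (0.143), and that of stress response genes without TGFβ replicate 2 (0.0515) or combined replicate 1 (0.081). Both also ended with thinned libraries. The stress response call ended as well with scaling by DESeq2 size factors, and the oxidative phosphorylation call with fry. Methionine and polyamine genes (adjusted p 0.1) were called lower without TGFβ replicate 2 (0.018) or combined replicate 1 (0.0465) and without TGFβ replicates 2 and 3 together. NAD metabolism genes (0 up, 5 down, adjusted p 0.35), senescence arrest genes (1 up, 4 down, 0.99), glycolysis genes (0.83) and histone methylation genes (0.35) were not called. The median or mean had the opposite sign to the test for basement membrane, fatty acid oxidation, aryl hydrocarbon receptor, lysosomal and ribosomal genes, none of which was called (adjusted p 0.2 to 0.83). Fry called 3 of the 10 lists that camera did not.

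**Figure D4:**
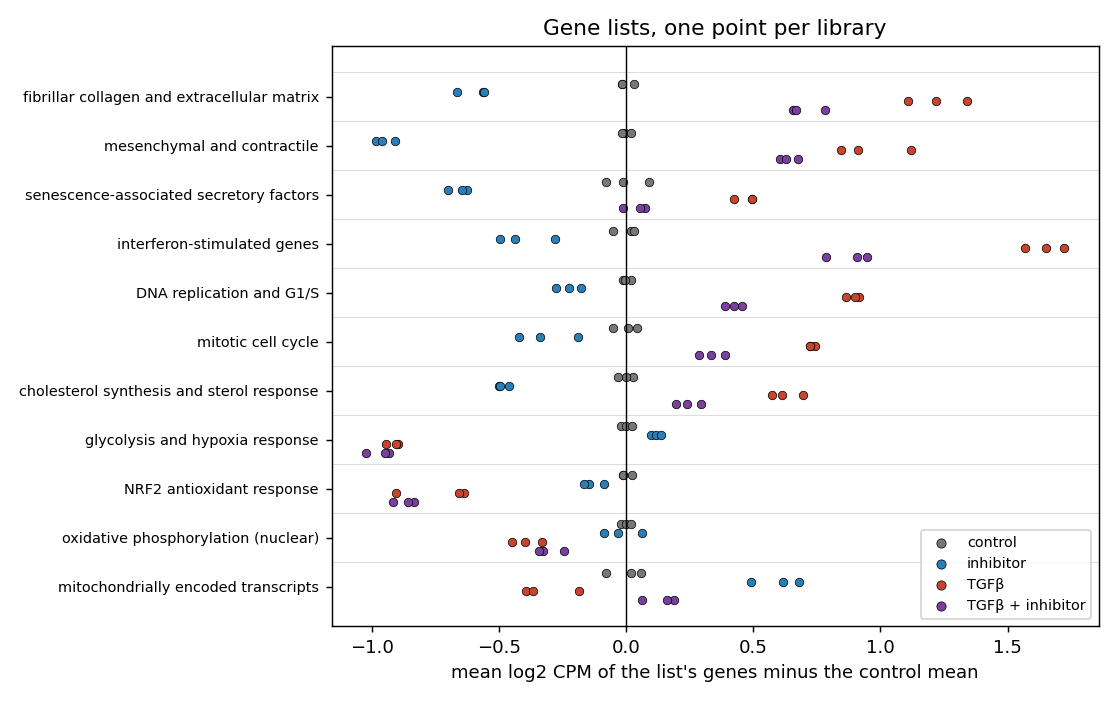
Mean log2 CPM of the genes of 11 lists, minus the control mean, with 1 point per library and a colour per group. For interferon-stimulated, DNA replication, mitotic and cholesterol synthesis genes, the combined libraries lie between the controls and the TGFβ libraries.

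Of the genes called with TGFβ, 507 rose and were then lower in the combined group, against 184 for independent lists, and 252 fell and were then higher, against 80.3. In the same direction, 44 were up in both comparisons, against 91, and 169 down in both, against 162. The opposite calls summed to 759. Both comparisons use the 3 TGFβ libraries, which cannot be split into groups of 2, so part of the excess may come from them. The covariance of the log2 fold changes over genes, which are not independent replicates, was -0.155, against means of 20 simulations of unchanged groups around the same TGFβ libraries of -0.0533 with the pooled spread and -0.078 with the spread of the TGFβ libraries. The correlation was -0.276, against -0.531 and -0.627. The simulated groups held no treatment effects, which add spread of their own to the real fold changes. These correlations therefore cannot be compared as strengths of opposite change. The number of opposite calls was 419 without combined replicate 3. The inhibitor's calls with and without TGFβ shared 112 rises, against 11.6, and 364 falls, against 54.9, such as *Ly6a*, *Postn*, *Havcr1* and *Fn1*, with 5 and 4 genes called in opposite directions, against 23.4 and 27.2. These comparisons share no library.

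The effect of TGFβ in the presence of the inhibitor was read from the combined group against the inhibitor, which has no library in common with TGFβ against control. *Acta2* rose 144-fold (7.16 ± 0.17, adjusted p 1.62e-15) from its lower starting level, while *Col1a1* rose 10.7-fold (adjusted p 2.22e-08). *Tagln* rose 51.4-fold, *Ccn2* 23.7-fold and *Fn1* 3.89-fold. *Havcr1* rose 7.78-fold, or 12.2-fold without inhibitor replicate 1. The metabolic hormone *Fgf21* had 0 counts with the inhibitor and 380 in the combined group, 135-fold higher at the floor (counting interval from 109). *Ctsw* had 2 counts against 1814, a ratio of 964 with a counting interval of 267 to 7970, the kinesin *Kif26b* 3 against 841 (ratio 298, interval 102 to 1450) and *C1qtnf3* 2 against 443 (ratio 235, interval 64.8 to 1950). Without inhibitor replicate 3 the fitted rise of *Ctsw* was 5040-fold, and without inhibitor replicate 2 that of *Kif26b* was 2350-fold. *Inmt* and the adhesion protein *Flrt1* reached 0 counts, 127-fold and 84.4-fold lower at the floor. Stanniocalcin (*Stc1*) fell 94.4-fold, *Aqp1* 86.5-fold and *Cdkl1* 82.4-fold. *Agt* fell 51.0-fold, or 83.3-fold without combined replicate 2.

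The arrest genes *Cdkn2b* and *Cdkn2a* rose 1.61-fold and 1.58-fold with TGFβ in the presence of the inhibitor, *Lmnb1* 1.70-fold and *Mki67* 1.55-fold (adjusted p 1.26e-05, 0.000827, 0.0022 and 0.00952). *Nnmt* rose 1.35-fold here (adjusted p 0.0396), a call that ended without inhibitor replicate 1 (0.192), inhibitor replicate 2 (0.073), combined replicate 1 (0.105) or combined replicate 2 (0.103). *Col4a1* fell 1.86-fold (adjusted p 0.0188), a call that ended without inhibitor replicate 1 (0.0605), inhibitor replicate 2 (0.0627), combined replicate 1 (0.0608) or combined replicate 2 (0.0701). *Cdkn1a* (0.6) and *Tgfb1* (0.315) were not called. Of 4933 called genes, 2448 were up and 2485 down, and 1820 rises and 1735 falls were shared with TGFβ against control, against 475 and 425 for independent lists. Camera called 15 lists, 8 up and 7 down, 13 with the estimated correlation, among them matrix genes (adjusted p 2.4e-16), contractile genes (1.2e-20) and interferon-stimulated genes (4.8e-24) up and glycolysis genes (1.7e-14) down. Also up were secreted senescence factors, mitotic, DNA replication, cholesterol and ribosomal genes, and also down proximal tubule, loop and distal, fatty acid oxidation and NRF2 genes. Oxidative phosphorylation (0.003, 0.29 with the estimated correlation) and lysosomal genes (0.045, 0.14) fell with the preset correlation but not with the estimated, and the lysosomal call ended without inhibitor replicate 3 (0.0503). The other 15 lists were not called (adjusted p 0.06 to 0.96), but fibroblast markers were without inhibitor replicate 2 (0.037), combined replicate 1 (0.0409) or combined replicate 2 (0.0403) and SMAD targets without combined replicate 1 (0.046), combined replicate 2 (0.0197) or combined replicate 3 (0.0281), SMAD targets also with a replicate block. Fry called 13 of these 15. Basement membrane genes had a median of the opposite sign to the test. Over the genes called with TGFβ alone, the slope of the TGFβ effect with the inhibitor on that without was 0.95 (jackknife SE 0.0785 over libraries, r 0.899, 4961 genes). Over the genes called with TGFβ in the presence of the inhibitor, the slope with exchanged axes was 0.755 (jackknife SE 0.0598, r 0.903, 4933 genes). The inhibitor effect with TGFβ on that without had a slope of 0.519 (r 0.705, 1123 genes called without), and the reverse 0.511 (r 0.642, 1416 genes called with). These slopes and correlations are across genes, which are not independent replicates. Choosing genes by their calls for the effect on the horizontal axis lowers a slope. A slope below 1 therefore need not mean a weaker effect.

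Whether the inhibitor effect differed with TGFβ was tested by the interaction, which held 151 genes, 87 positive and 64 negative, with 37 and 41 of at least 1 on the log2 scale. *Acta2* had the smallest adjusted p, falling 9.29-fold with the inhibitor alone and not called with TGFβ (interaction 2.84 ± 0.20, adjusted p 3.78e-07). The mechanosensitive *Ankrd1* (1.38 ± 0.15, adjusted p 0.000134), the actin bundler *Fscn1* (1.25), fibromodulin (*Fmod*, 1.52) and the matrix-binding *Ccbe1* (1.62) were also positive, each with an adjusted p of 0.000173 or lower. The transcription factor *Sox9* was higher with the inhibitor alone, at 171 ± 4.67 against 129 ± 4.71 CPM, and lower in the combined group than with TGFβ, at 38.4 ± 1.05 against 81.5 ± 8.03 CPM (interaction -1.50 ± 0.14, adjusted p 1.24e-05). Also negative were the histone genes *Hist1h1c* (-1.74) and *Hist1h2bc* (-1.88), the glutathione enzyme *Gclc* (-1.16) and *Flrt1*. The last had 85 counts with TGFβ and 0 in the combined group, 30.7-fold lower at the floor. *Col1a1* was negative (-1.76 ± 0.36, adjusted p 0.0291), a call that ended without control replicate 2 (0.0977), control replicate 3 (0.0656), inhibitor replicate 2 (0.126), inhibitor replicate 3 (0.0925), combined replicate 2 (0.0735) or combined replicate 3 (0.0778). *Tagln* was positive (2.46 ± 0.46, adjusted p 0.0356), a call that ended without control replicate 1 (0.093), control replicate 2 (0.0897), control replicate 3 (0.0608), inhibitor replicate 2 (0.0801), inhibitor replicate 3 (0.0783), TGFβ replicate 1 (0.0714), combined replicate 1 (0.0638) or combined replicate 3 (0.0628). *Fn1* (0.459) was not called but was without TGFβ replicate 2 (0.00173), and *Havcr1* (0.542), *Nnmt* (0.681), *Cdkn2b* (0.84) and *Cdkn2a* (0.968) were not called.

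The number of interaction genes was 79, 65 or 73 without control replicate 1, 2 or 3, 93 without inhibitor replicate 1, 81 without inhibitor replicate 2 or 3, 92 or 91 without combined replicate 1 or 3, and 399 without TGFβ replicate 2. Camera called 11 lists, 7 positive and 4 negative, of which 2 held with the estimated correlation. Mesenchymal and contractile genes were positive, 9 up and 0 down of 27, and 13 and 1 adjusted over the list alone (median 0.56, adjusted p 1.3e-20, 0.0035 with the estimated correlation), having fallen with the inhibitor alone and less so with TGFβ. DNA replication genes were negative, 0 up and 1 down of 45, and 0 and 1 adjusted over the list alone (median -0.27, adjusted p 6.7e-05, 0.029 with the estimated correlation). Interferon-stimulated genes were negative, 0 up and 3 down of 49, and 0 and 12 adjusted over the list alone (median -0.33, adjusted p 3e-08), but not with the estimated correlation (0.15). Also called with the preset but not the estimated correlation were glycolysis (0.01, 0.057 estimated) and loop and distal genes (0.016, 0.19), negative, and stress response (0.01, 0.055), matrix (0.016, 0.2), SMAD (0.034, 0.2), oxidative phosphorylation (0.045, 0.46), basement membrane (0.049, 0.15) and secreted senescence factor genes (0.027, 0.1), positive. The median of the secreted factors was -0.00176 and above 0 under the other 2 scalings.

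Single libraries changed several list calls of the interaction. The call ended for matrix genes without combined replicate 1 (0.0669), for glycolysis genes without combined replicate 1 (0.0507) and for basement membrane genes without control replicate 1 (0.11), inhibitor replicate 2 (0.0839), inhibitor replicate 3 (0.072), TGFβ replicate 1 (0.0648), TGFβ replicate 2 (0.0669), TGFβ replicate 3 (0.0919) or combined replicate 1 (0.11). It ended for loop and distal genes without control replicate 1 (0.0511), control replicate 2 (0.0671), inhibitor replicate 3 (0.0574), TGFβ replicate 2 (0.118), combined replicate 1 (0.0538) or combined replicate 2 (0.101), and for oxidative phosphorylation genes without control replicate 2 (0.0513), control replicate 3 (0.0764), inhibitor replicate 1 (0.131), TGFβ replicate 1 (0.267) or combined replicate 2 (0.144). It ended for secreted senescence factors without control replicate 1 (0.0982), TGFβ replicate 1 (0.0771) or combined replicate 1 (0.0669), and for SMAD targets without control replicate 1 (0.0982), inhibitor replicate 1 (0.0571) or combined replicate 1 (0.123). With thinned libraries the calls of basement membrane, oxidative phosphorylation and secreted factor genes ended as well. Scaling by DESeq2 size factors also ended the basement membrane call, and fry those of matrix, SMAD and oxidative phosphorylation genes. The other 19 lists were not called (adjusted p 0.053 to 0.92), but cholesterol genes were without control replicate 3 (0.0476), inhibitor replicate 2 (0.0489), TGFβ replicate 2 (0.0356), combined replicate 2 (0.0341) or combined replicate 3 (0.0469), mitochondrially encoded transcripts without TGFβ replicate 2 (0.0106) and NF-kB targets without control replicate 3 (0.0476), inhibitor replicate 1 (0.0391), TGFβ replicate 1 (0.0114), TGFβ replicate 3 (0.0423) or combined replicate 3 (0.0469). Fry called 3 of these 19. Podocyte, senescence arrest, methionine and ribosomal genes had a median or mean of the opposite sign to the test.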

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

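These results were picked out because the inhibitor effect differed between cells with and without TGFβ in a test of that difference, the interaction. The list tests of the interaction were added after the data were seen, and the gene tests were planned. The values are log2 differences of the inhibitor effect, with TGFβ minus without. They were positive for *Acta2* (2.84), *Tagln* (2.46), *Ccbe1* (1.62), *Fmod* (1.52), *Ankrd1* (1.38) and *Fscn1* (1.25), and negative for *Col1a1* (-1.76), *Sox9* (-1.50), *Hist1h1c* (-1.74), *Hist1h2bc* (-1.88) and *Gclc* (-1.16). *Flrt1* had 0 counts in the combined group, so its value is -4.66 with 3 counts over the group in place of 0, a form chosen after its values were seen. The call of *Tagln* ended without control replicate 1 (0.093), control replicate 2 (0.0897), control replicate 3 (0.0608), inhibitor replicate 2 (0.0801), inhibitor replicate 3 (0.0783), TGFβ replicate 1 (0.0714), combined replicate 1 (0.0638) or combined replicate 3 (0.0628), and that of *Col1a1* without control replicate 2 (0.0977), control replicate 3 (0.0656), inhibitor replicate 2 (0.126), inhibitor replicate 3 (0.0925), combined replicate 2 (0.0735) or combined replicate 3 (0.0778).

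Of the gene lists, mesenchymal and contractile genes had a median difference of 0.555 and DNA replication genes a median difference of -0.274, and both passed with the preset and the estimated correlation. With 3 libraries per group, no sample was tested as an outlier within its group.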

How the results depend on the processing

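Quality weights, thinning to 2584117 counts, and leaving out TGFβ replicates 2 and 3 were chosen after the data were seen. A count was taken as the same if it lay within 1.5 times the main count, and a slope if within its jackknife SE. On that scale, 149 alternative values stayed the same and 40 moved among slopes and counts of called genes, opposite calls and called lists. For single lists 1756 calls stayed, 87 were lost and 67 gained. For named genes, 9287 stayed, 509 lost and 48 gained a call, and none reversed in any group of results. A log2 fold change of at least 1 left 1749 genes for TGFβ, 365 for the inhibitor, 449 for the inhibitor with TGFβ, 1894 for TGFβ with the inhibitor and 78 for the interaction. Thinning left 709 for the inhibitor, 782 for the inhibitor with TGFβ, 82 for the interaction and 442 opposite calls. With only the 2 groups compared, the inhibitor alone had 2931 genes and the inhibitor with TGFβ 408. The interaction had 260 genes in DESeq2, 306 without a filter and 483 with quality weights. Without TGFβ replicates 2 and 3, where the lone TGFβ library is assumed to vary like the others, the interaction had 350 genes, opposite calls 470, and the slope of TGFβ effects was 0.859. Without a filter the 2 slopes were 0.796 and 0.69. With the estimated correlation, 13 lists were called for the inhibitor with TGFβ. The 2-group counts shifted in the direction that the unequal spread of the groups would give. The cause of the shifts was not tested, and the alternatives planned for normalized values were not run because the table holds counts. Leaving out 1 library gave 4038 to 5166 genes for TGFβ, 591 to 684 for the inhibitor, 762 to 1938 for the inhibitor with TGFβ, 4098 to 4395 for TGFβ with the inhibitor, 65 to 399 for the interaction and 419 to 1038 opposite calls. The slopes ranged from 0.866 to 0.943, each below the 0.95 of all libraries, and from 0.695 to 0.769, and called lists from 14 to 17, 14 to 15 and 17 to 20.

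The replicate numbers did not pair the samples. Correlations of 18 pairs with the same number ranged from -0.085 to 0.2, 1 of them over 0.1, and 5 of 12 samples matched best with their own number. A replicate block gave 4875 genes for TGFβ, 1033 for the inhibitor, 1306 for the inhibitor with TGFβ, 4887 for TGFβ with the inhibitor, 119 for the interaction and 717 opposite calls.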

Other observations

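Antigen presentation genes that interferon-gamma induces through CIITA moved against the interferon-stimulated genes in the 2 comparisons that test TGFβ, and the difference between the lists was not tested. This list and the tests below were chosen after the results were seen, except thinning for the spread of TGFβ replicate 2, leaving that library out of the interferon list, and the other splits of the libraries. With TGFβ, 6 of 7 tested genes fell (*Ciita*, *Cd74* and class II genes such as *H2-Aa* make up the list) with a median of -1.50 on the log2 scale, and with TGFβ in the presence of the inhibitor 6 of 7 fell with a median of -1.75. With the inhibitor alone 1 fell and none rose, though the median was 0.258, opposite in sign to the interferon-stimulated genes, and with the inhibitor on top of TGFβ 1 rose and 1 fell, with a median of the same sign as the interferon-stimulated genes (-0.378). A list of 4 tested interferon-gamma genes outside CIITA (*Irf1*, *Socs1*, *Socs3*, *Cd274*) had 0 called genes with TGFβ, 0 with the inhibitor and 2 up with TGFβ in the presence of the inhibitor. Nuclear-retained non-coding transcripts had 1 of 7 up with the inhibitor (*Firre*, adjusted p 0.0198). The only tested leukocyte gene, *Fcer1g*, rose with TGFβ by a log2 of 1.87.

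A test below leaves out the mitochondrially encoded genes, *Malat1* and *CT010467.1*. Its library-size form replaced a TMM form (2.35 falls per rise with and 2.36 without those genes) that could not have moved.

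TGFβ replicate 2 stood apart from the other TGFβ libraries, and replicate 3 did so to a lesser degree (0.201 from replicate 1 with thinned libraries, against at most 0.147 between controls). The cause of the latter was not tested. Reads placed differently between pseudogenes and their parent genes may add to the spread, though read placement itself was not measured. Over 152 pseudogenes, replicates 2 and 1 differed by 0.604, against at most 0.169 between controls. Replicates 3 and 1 differed there by 0.525, and replicates 2 and 3 by 1.04, so replicate 3 departed as well. Over 8775 protein-coding genes, replicates 2 and 1 differed by 2.33 times the largest control pair. That difference was known before and is part of what set replicate 2 apart, so pseudogenes are not the whole of the pattern. With every library thinned, replicates 2 and 1 still differed by 1.97 times the largest control pair, which argues against unequal depth of these 2. The shallow replicate 3 is in neither place, so its depth was not tested by this. The position of replicate 2 of -0.104 on the inhibitor signature, with the combined libraries at 0.991 to 1.01, argues against an unlabelled inhibitor treatment. No biological explanation was tested.

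Mitochondrial transcripts and *Malat1* were higher with the inhibitor alone, and falls outnumbered rises. That excess depended on the fit, with 335 genes up and 788 down in the model of all libraries. Fitting only these 2 groups gave 1287 up and 1644 down, a smaller excess relative to the rises. Loss of cytoplasmic RNA would raise other nuclear-retained transcripts as well, but the median of the 7 tested was 0.0762 (SD 0.367) against 0.799 for *Malat1*. The set was chosen without *Neat1*. Its changes ran from -0.318 (*Pvt1*) to 0.678 (*Ftx*), and some members were low, *Ftx* at 2.08 CPM in the controls. The next test left out 39 genes, the mitochondrially encoded ones, *Malat1* and *CT010467.1*, so it covers the same transcripts that were higher. They held 13.3% of control and 18.9% of inhibitor counts. With library-size scaling, leaving them out lowered falls per rise from 5.08 to 1.75, with 2.4 to 3.14 when 1 library was left out. Falls still led, which argues against these genes as the whole cause. Their share fixes the direction of that drop and the TMM ratio barely moved without them, so whether they account for part of the excess cannot be read from it. An effect of the inhibitor itself stays open.

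Interferon-stimulated genes were higher with TGFβ and lower with the inhibitor. With the inhibitor alone that fall was called with the preset correlation (adjusted p 3.6e-09) but not with the estimated (0.063). Immune cells could bring such transcripts, but summed leukocyte CPM rose from 1.6 to 5.32 and interferon-stimulated CPM from 6630 to 14100, a share of 0.000501. Without TGFβ replicate 2 the list median was 1.6 against 1.76 (adjusted p 4.13e-51), so that library was not the source. Any interferon-gamma left from the 33 °C medium came from a history that all groups shared, so alone it would not make them differ. A stronger response to it with TGFβ would raise its other targets by about as much. The 4 tested of 8 genes outside CIITA had a median of 0.0649 (SD 0.214) and none was called. These 4 genes thus did not follow the list with TGFβ alone. With TGFβ in the presence of the inhibitor, their median was 0.466 and 2 were called higher. So few genes, chosen after the results were seen, cannot stand for all targets of interferon-gamma, so such a response is not excluded. The bound for this test, the list median of 1.76, replaced a bound of 0 after these values were seen. An effect of the treatments stays open.

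The splits of 3 libraries against 3 number 10, too few for a share under 0.05. The real split was the only 1 of 10 with as many genes in each of the 4 comparisons, with 4961, 1123, 1416 and 4933 genes against at most 0 in any other. For lists it was also 1 of 10, with 16, 14 and 20 lists against at most 13, 13 and 8, so camera with a preset correlation called many lists in other splits too. Each other split leaves part of the treatment difference between its sides. Its list calls thus do not measure how many lists chance alone would give. For the interaction, 3 of 100 groupings had as many genes as the real 151, the highest other being 6219. The 2 others put all 6 TGFβ-treated libraries on 1 side, which points to the structure of the samples. For opposite calls, 2 of 100 groupings reached the real 759, the other with 2920 genes. Most other groupings mix libraries with and without TGFβ, which widens the spread within groups and leaves few calls, so these counts do not exclude chance.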
